A study of Homo sapiens with 4 samples.

How the data were processed

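The series holds 4 arrays of MDA-MB-231 cells, 1 per group: parental cells and cells with a KAP1 (TRIM28) short hairpin RNA, each with glucose or after 8 h without glucose. Per the labels, cells grew in DMEM with 10% serum, RNA was taken with Trizol and RNeasy columns with DNase I, and biotin-labelled cRNA was made with a MessageAmp kit for Illumina bead arrays. The treatment text of the labels gives glucose-free medium for every sample, while the sample titles and the stress field tell fed and starved samples apart, and the titles were followed. Image analysis software, probe annotation build and array scanner settings are not given in the sources used here.

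The main table gives, per the file headers, the mean bead intensity of 47228 probes on each array, on a linear scale and not normalized between arrays, with no background subtraction seen in the values. The same deposited table gives the standard error over beads, the number of beads and a detection p-value for each probe and array, and the detection p-values move in steps of 1 in 770. The authors also deposited a value table with the intensity of each probe quantile normalized over the 4 arrays, on a linear scale; this was read from its values, since its 4 columns have near-equal quantiles with a median of 129 each. Its probe identifiers are not those of the main table, and 42787 of its entries have the same ranks on all 4 arrays as a probe of the main table. It was therefore used for counts of probes without gene names, as an alternative.

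Intensities were background corrected with normexp from the detection p-values, given an offset of 16, quantile normalized and taken to log2 with neqc of limma 3.58.1 in R 4.3.3. Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A probe counted as detected at a detection p under 0.01, and genes entered when a probe was detected on at least 1 array. Of the probes, 43958 carry a symbol, 35669 had an Entrez identifier that matched the RefSeq table of genes, and 8788 symbols were updated by it. Of 3532 genes with several detected probes, the probe with the highest mean log2 signal was used. Other detected probes that differ are mentioned for some of the named genes only. Genomic coordinates are not given, since the probe annotation names no chromosome or genome build. In all, 13798 genes were counted.

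Differences are log2 signals of 1 array minus another, positive when higher in starved or in knockdown cells. Genes at 2-fold or more were counted, and at 1.5-fold beside them. A 95% bead interval was computed from the bead standard errors and covers bead scatter only, with a median half-width of 0.26 for either starvation difference, 0.28 and 0.24 for the knockdown differences with and without glucose and 0.37 for the difference of responses. Genes undetected on the dimmer array were given as a bound, "at least N-fold", against the lowest signal among detected probes of that array. The percentage of probes detected was between 35.6% and 37.3% per array. Arrays were not tested one against one, since each group has 1.

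The test used was limma with starvation and line as additive terms on the 4 arrays, with 1 residual degree of freedom, which is the disagreement between lines, then eBayes and a Benjamini-Hochberg adjusted p under 0.05, two-sided. The prior had 4.07 degrees of freedom. The fit was tested on simulated data of the same size with planted effects and no disagreement between the lines beyond noise, and made 5 false calls for starvation and 8 for the knockdown. The noise was drawn from the prior of the fit itself, without a dependence on intensity. The size of the response in the lines was compared in genes chosen by their mean response over both, which favours the line with the wider spread, so the share was also computed with both differences brought to equal SD over all genes, a reference added after the result was seen. Overlaps were compared with the product of both counts over all genes.

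For 29 gene lists written before the data were examined, the median log2 difference was placed among those of 10000 random lists of the same size matched in 20 bins of mean signal, and members passing limma were counted over all genes and adjusted over the list alone. The lists cover integrated stress response targets, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, glycolysis, HIF targets, arrestin-domain genes, hexosamine, pentose phosphate, cholesterol and fatty acid synthesis, mitochondrial fusion and fission, tricarboxylic acid cycle, respiratory chain, autophagy, DNA replication, mitosis, p53 pathway, imprinted, interferon, inflammatory, immediate early, heat shock, NRF2, mesenchymal, ZNF and ribosomal protein genes, and markers of luminal, leukocyte and kidney or neuronal-type cells.

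Genes are named by a rule: TRIM28; in each comparison and in the difference of responses the 8 largest and 8 smallest log2 differences among genes detected on every array used and with a settled symbol; the 10 largest and 10 smallest called genes of each averaged effect; up to 4 members per list with the largest difference in the comparison described; and MFN1, MFN2, OPA1 and DNM1L always. Exceptions are said where they occur.

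Alternatives tried were no background correction, an offset of 50, median scaling, the deposited value table, other detection filters, the mean of the probes of a gene or every probe on its own, thresholds of 1.5-fold and 3-fold, an adjusted p under 0.1, a minimum fold of 1.2, and other variance priors. Leaving out an array was not possible. No per-sample column was left unused (0 columns).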

Results

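Messenger RNA levels were measured in MDA-MB-231 cells, a human triple-negative breast cancer cell line, on an Illumina bead array that reads biotin-labelled cRNA. The 4 groups were parental cells kept with glucose, parental cells after 8 h without glucose, and the same 2 conditions in cells carrying a short hairpin RNA against KAP1. Each group held 1 array, and no array came from cells with a nontargeting hairpin, so each knockdown difference is against the parental line. Every array carried 47228 probes, with a median of 22 beads per probe. The median raw intensity was 116 for parental cells with glucose, 138 for starved parental cells, 129 for knockdown cells with glucose and 131 for starved knockdown cells. In the same order, 16824, 17161, 16931 and 17599 probes were detected. Pearson's r of the log2 signals across probes lay between 0.978 and 0.988 for every pair of arrays, and probes are not independent replicates. In all, 13798 genes were detected on at least 1 array and 11532 on all 4. There are no replicates, the number of arrays limits the precision, and the 95% bead intervals given with a difference cover the scatter between beads of 1 array only.

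KAP1 is the corepressor that KRAB zinc finger proteins bring to chromatin, and TRIM28 (Entrez Gene 10155) encodes it. TRIM28 transcripts were about 9-fold lower in both knockdown cultures than in the parental ones, a fold that depends on background correction. The normalized log2 level of TRIM28 was 10.00 in parental cells with glucose and 9.83 after starvation, against 6.71 and 6.58 in knockdown cells. Raw intensities were 1034 and 1143 in the parental cultures and 199.8 and 200.02 in the knockdown cultures. The knockdown difference was -3.30 with glucose (95% bead interval -3.59 to -3.0), a 9.82-fold lower level. In starved cells it was -3.24 (interval -3.53 to -2.96), a 9.48-fold lower level. Without background correction the differences were -2.45 and -2.36. The TRIM28 difference with starvation was small, -0.17 in parental cells (interval -0.36 to 0.02) and -0.12 in knockdown cells (interval -0.48 to 0.24). The array has 1 detected probe for TRIM28, and it was detected on all 4 arrays. The plot of levels by array shows TRIM28 beside other genes picked by the naming rule.

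**Figure D1:**
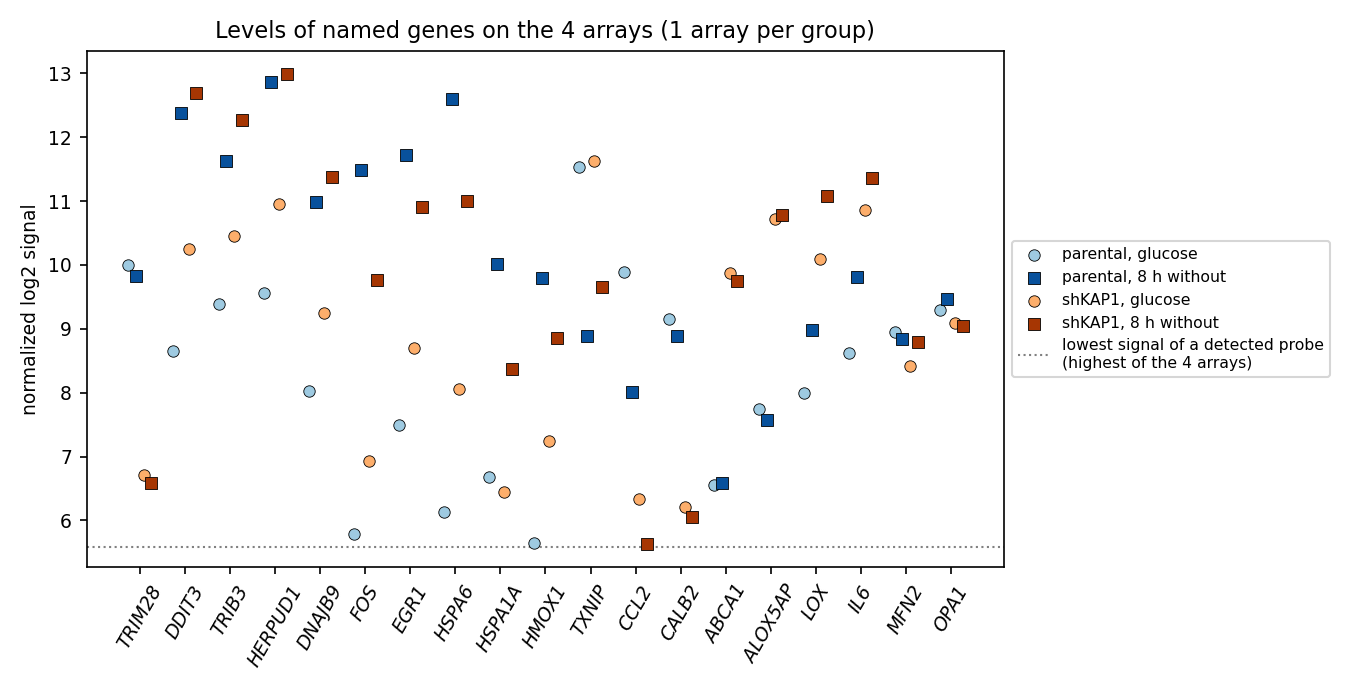
Normalized log2 signal (vertical axis) of TRIM28 and other named genes (horizontal axis), with 1 point per array, circles for cells with glucose, squares for 8 h without, blue for parental and orange for knockdown cells, and a dotted line at the lowest signal of a detected probe. TRIM28 lies at 10.00 and 9.83 in parental cells and at 6.71 and 6.58 in knockdown cells.

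The series title asks which genes respond to loss of glucose in the parental and in the knockdown line, and the starvation difference of the parental line comes first. After 8 h without glucose, parental cells carried far more transcript for stress-inducible transcription factors and chaperones. HSPA6, an inducible HSP70 chaperone, was 88.4-fold higher (log2 difference 6.47, bead interval 6.16 to 6.77), and a second HSPA6 probe gave 4.62. The immediate early transcription factors FOS, FOSB and EGR1 were 51.8-fold, 19.4-fold and 18.8-fold higher. HMOX1, which encodes heme oxygenase, was 17.7-fold higher (interval 3.78 to 4.51 on the log2 scale). DDIT3, which encodes the stress transcription factor CHOP, was 13.3-fold higher (interval 3.48 to 3.98). At the other end lay TXNIP, a glucose-dependent transcript whose product restrains glucose uptake. TXNIP was 6.22-fold lower (-2.64, interval -2.84 to -2.44). The chemokine gene CCL2, the G protein signalling regulator RGS4 and the RNase P RNA gene RPPH1 were 3.66-fold, 3.82-fold and 3.62-fold lower. The HSPA7 pseudogene and MT1P3 were 24.7-fold and 21.2-fold higher, but close paralogs of both exist, so the identity of these transcripts is uncertain.

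Amino acid and endoplasmic reticulum stress genes had higher medians in starved parental cells. The 33 measured targets of the integrated stress response, which the transcription factor ATF4 induces, had a median log2 difference of 0.89, at percentile 100 of 10000 random lists matched on expression. Of these, 25 were at least 1.5-fold higher, 16 at least 2-fold higher and 0 at least 1.5-fold lower. Among them, CTH of cysteine synthesis was 8.23-fold higher and ATF3 7.05-fold higher. SESN2, an inhibitor of mTORC1, was undetected with glucose and at least 4.45-fold higher without it. The 21 genes of the aminoacyl-tRNA synthetase list, which also holds the tRNA export gene XPOT, had a median of 0.25 (percentile 100). Of these, 5 were at least 1.5-fold higher, among them AARS1 (1.0), CARS1 (0.83) and GARS1 (0.74). The 30 endoplasmic reticulum chaperone and degradation genes had a median of 0.74 (percentile 100), 20 of them at least 1.5-fold and 9 at least 2-fold higher. In this group HERPUD1, of the degradation machinery, was 9.89-fold higher and the cochaperone gene DNAJB9 7.72-fold higher, with SYVN1 at 1.70 and SDF2L1 at 1.59.

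Immediate early and antioxidant genes also had higher medians in starved parental cells, while inflammatory genes went both ways. The 33 immediate early and MAPK feedback genes had a median of 0.36 (percentile 100), 16 of them at least 1.5-fold higher and 1 at least 1.5-fold lower. EGR2 was undetected with glucose and at least 4.53-fold higher without it. Among 21 heat shock genes the median was 0.10 (percentile 98.5, or 94.4 without background correction), and 4 were at least 2-fold higher, among them HSPA1A (3.33), HSPA1B (2.02) and DNAJB1 (1.89); HSPA1A and HSPA1B are near-identical, so which of them was read is uncertain. The 19 NRF2 antioxidant targets had a median of 0.33 (percentile 100), with OSGIN1 at 1.83 and the ferritin gene FTH1 at 0.91. Of 26 inflammatory cytokine and NF-kB targets, 7 were at least 2-fold higher and 1 lower, with PTGS2 4.77-fold higher, NFKBIZ 4.02-fold higher and IL24 3.80-fold higher; the median was 0.11 (percentile 95.4), with 13 members above 0 and 13 below. The 21 growth arrest and apoptosis genes of the p53 pathway had a median of 0.32 (percentile 100), which was 0.13 (percentile 98.2) without background correction and 0.18 with an offset of 50, led by the DNA damage response genes GADD45A (2.01) and GADD45B (1.56). The 24 type I interferon response genes had a median of -0.24 (percentile 1.05, or 2.6 without background correction), with 16 below 0 and 8 above, and 6 were at least 1.5-fold lower, among them IFIT1 (-1.28) and the RNA sensor gene RIGI (-1.04).

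Among metabolic lists, the TXNIP family and glycolysis genes had the lower medians in starved parental cells. In the TXNIP family of 4 arrestin-domain genes, 3 were at least 1.5-fold lower, and the median was -0.89 (percentile 0, or 3.6 with the mean of all probes of a gene). The family median was -0.45 without background correction and -0.64 with an offset of 50. ARRDC2 was at -0.82 and ARRDC4, undetected after starvation, was at least 1.5-fold lower. The 23 glycolysis and glucose transport genes had a median of -0.17 (percentile 0.85, or 5.9 without background correction) and 17 members below 0, with PFKFB4 at -0.91 and ENO2 at -0.61 but HK2 at 0.73 and SLC2A3 at 0.72. The 20 hexosamine and nucleotide-sugar genes had a median of 0.13 (percentile 96.5), with UGDH at 0.76, OGT at 0.74 and GFPT1 at 0.60. The 19 hypoxia-inducible factor (HIF) targets outside glycolysis had a median of 0.03 (percentile 73.2), with ANGPTL4 4.34-fold higher and BHLHE40 at 1.03. The 55 nuclear respiratory chain genes had a median of -0.09 (percentile 2.44, or 3.35 with the mean of all probes), which turned to 0.04 when the arrays were scaled by their median instead. The medians of DNA replication (-0.14, percentile 2.59), mitosis (-0.05, percentile 34.5), autophagy and lysosome (-0.10, percentile 11.4) and fatty acid synthesis genes (-0.13, percentile 13.1) also became positive under that scaling. Members furthest from 0 were CDT1 (-0.83) and FEN1 (-0.67) in replication, MKI67 (-0.85) and KIF20A (-0.68) in mitosis, WIPI1 (1.06) and MAP1LC3B (0.88) in autophagy, and SREBF1 (-1.22) and SCD (-0.65) in fatty acid synthesis. The medians were -0.03 for cholesterol genes (percentile 51.2), with HMGCS1 at 1.10, and -0.06 for the pentose phosphate pathway (percentile 37.7), and both changed sign with median scaling. Mesenchymal genes had a median of 0.04 (percentile 79.0), with MMP3 at 1.62 and THBS1 at 1.14.

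In all, 273 genes were at least 2-fold higher and 163 at least 2-fold lower in starved than in fed parental cells, 436 together. Of these, 201 and 102 were detected on both arrays, and 434 differed by more than their bead interval. With median scaling the split was 396 higher and 112 lower, and without background correction 134 genes passed in all. At 1.5-fold the counts were 1061 and 992. With 1 array on each side, no test was possible within the parental line.

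In the knockdown line the integrated stress response, aminoacyl-tRNA synthetase and endoplasmic reticulum lists were also higher after starvation, with medians of 0.90, 0.33 and 0.63 against 0.89, 0.25 and 0.74 in parental cells. HSPA6 was 7.76-fold higher (2.96, interval 2.66 to 3.25), FOS 7.11-fold, DDIT3 5.42-fold (interval 2.25 to 2.62) and EGR1 4.61-fold. TXNIP was 3.92-fold lower (-1.97, interval -2.17 to -1.77), RPPH1 was at -1.69, and the WNT feedback gene AXIN2 at -1.10. The integrated stress response list had its median at percentile 100, with 23 of 33 at least 1.5-fold and 11 at least 2-fold higher and 0 at least 1.5-fold lower. The growth factor gene GDF15 was at 2.03, SESN2 at 1.88, and ADM2, undetected with glucose, was at least 3.37-fold higher. The aminoacyl-tRNA synthetases were also at percentile 100, with AARS1 at 0.90 and WARS1 at 0.66. The endoplasmic reticulum list was at percentile 100, with 11 of 30 at least 2-fold higher, DNAJB9 4.37-fold, HERPUD1 4.10-fold and ERO1B 1.61 on the log2 scale.

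Other lists of the knockdown line after starvation were closer to 0. Immediate early genes had a median of 0.19 (percentile 100), 7 of 33 at least 2-fold higher, and heat shock genes -0.03 (percentile 42.4), with HSPA1A at 1.92 and DNAJB1 at 0.99. NRF2 targets had a median of 0.14 (percentile 99.0, but 91.6 with median scaling and 96.7 with the mean of all probes), with HMOX1 at 1.61 and OSGIN1 at 1.09. Inflammatory genes had a median of 0.12 (percentile 99.1), with PTGS2 at 0.96 and NFKBIZ at 0.95. HIF targets had a median of 0.26 (percentile 100), with ANGPTL4 at 1.36 and LOX, a collagen crosslinking enzyme gene, at 1.0. Mitosis genes were lower, with a median of -0.19 (percentile 0), 30 of 34 below 0 and MKI67 at -0.75, and DNA replication genes had a median of -0.12 (percentile 0.805). Interferon genes were at -0.13 (percentile 4.18), with IFIT1 at -1.06. Hexosamine (0.11, percentile 98.0) and autophagy genes (0.09, percentile 99.1) lay above random lists, the hexosamine genes no longer so with median scaling. Glycolysis (0.01, percentile 70.9), p53 pathway (0.08, percentile 90.2), cholesterol (0.06, percentile 90.6) and fatty acid synthesis genes (-0.12, percentile 4.98) lay inside the central range, as did mesenchymal genes (0.02, percentile 72.6). With the mean of all probes, the p53 pathway median was 0.27 (percentile 99.9) and the cholesterol median 0.12 (percentile 98.6), both above random lists. The medians were -0.14 for the TXNIP family (percentile 22.1), -0.02 for the pentose phosphate pathway (percentile 48.6) and -0.07 for the respiratory chain (percentile 4.80), the last 2 changing sign with median scaling.

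In the knockdown line, 111 genes were at least 2-fold higher and 57 at least 2-fold lower after starvation, 168 together, of which 70 and 21 were detected on both arrays. With median scaling the split was 137 and 43, and without background correction 40 genes passed in all. At 1.5-fold the counts were 628 and 481. Between the lines, 67 genes were at least 2-fold higher in both, where independent lists would share 2.20, and 10 were at least 2-fold lower in both, where independent lists would share 0.673. No gene was at 2-fold in opposite directions (0 genes), and Pearson's r of the responses across genes, which are not independent replicates, was 0.488. Of the 273 genes higher in parental cells, 259 were also higher in knockdown cells, and of the 163 lower ones, 134 were also lower.

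The starvation effect averaged over both lines was tested with limma, where the only residual is the disagreement between the lines. After adjustment over 13798 genes, limma called 0 genes, with a smallest adjusted p of 0.120, two-sided. At an unadjusted p under 0.05 there were 2241 genes, and with an intensity trend and a robust prior limma called 981 genes, 532 higher and 449 lower. Adjusted over the list alone, 26 integrated stress response targets, 7 genes of the aminoacyl-tRNA synthetase list (XPOT among them), 23 endoplasmic reticulum genes and 13 immediate early genes passed, all higher. By the same count, 7 heat shock genes passed as higher and 1 (HSPA8) as lower, and 8 inflammatory genes as higher and 2 (CCL2 and CXCL1) as lower; HSPA8 and CXCL1 are named after their values were seen. The HIF targets ANGPTL4, LOX, BHLHE40, ANKRD37 and VEGFA, the NRF2 targets HMOX1 and OSGIN1, and GADD45A and GADD45B of the p53 list passed as higher. In the TXNIP family ARRDC3 passed as higher and TXNIP and ARRDC4 as lower, and in their lists WIPI1 passed as higher and IFIT1 as lower. Over all genes, 0 members of any list passed. HSPA6, FOS and DDIT3 averaged 4.71, 4.26 and 3.08 and did not pass, with adjusted p of 0.176, 0.176 and 0.162 in limma, while their responses differed between the lines. In simulated data without such differences the same fit called 25.4% of planted log2 starvation effects of 1 and 100% of those of 2, rates that do not apply to genes whose lines differ.

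Responses to starvation were smaller in the knockdown line for most responding genes, and the parental differences were more widely spread over all genes. Of 169 genes whose mean response over both lines was at least 2-fold, 154 (91.1%) had the smaller response in knockdown cells. The median response in the shared direction was 1.67 in parental and 1.01 in knockdown cells, and the median difference was -0.74. Over all 13798 genes the starvation differences had an SD of 0.46 in parental and 0.34 in knockdown cells, and normal values with those spreads and their correlation would give a share of 86.8%. With both differences brought to equal SD, 103 of 162 responding genes (63.6%, 95% bootstrap interval 56.2% to 71.0%) had the smaller response in knockdown cells. Without that scaling the response was smaller for 123 of 132 higher genes and 31 of 37 lower genes, and for 126 of 136 genes (92.6%) detected on all 4 arrays. The response of HSPA6 was smaller by -3.51 on the log2 scale (knockdown minus parental, interval -3.94 to -3.08), that of FOS by -2.86 and that of HMOX1 by -2.54. The metallothionein genes MT1E (-2.19) and MT1G (-2.18) were among the 8 most negative, although the close members of this family cannot be separated here. Among positive differences were GPER1, a membrane estrogen receptor gene, at 1.71 (interval 1.12 to 2.29), SLCO4A1 at 1.37 and the glutamate transporter gene SLC1A3 at 1.26. They were lower after starvation in parental cells, at -1.62, -1.32 and -1.50, and nearer 0 in knockdown cells, at 0.09, 0.05 and -0.24, so their responses were smaller too. FNIP2, at 1.74 (interval 0.63 to 2.84), was at -0.54 in parental and 1.19 in knockdown cells. At 2-fold, 181 genes had a more positive and 216 a more negative response in knockdown cells, 397 together, of which 33 and 86 were detected on all 4 arrays. With median scaling the split was 140 and 277, and without background correction 35 genes passed in all. This difference of responses leaves no residual with 4 arrays and was not tested.

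**Figure D2:**
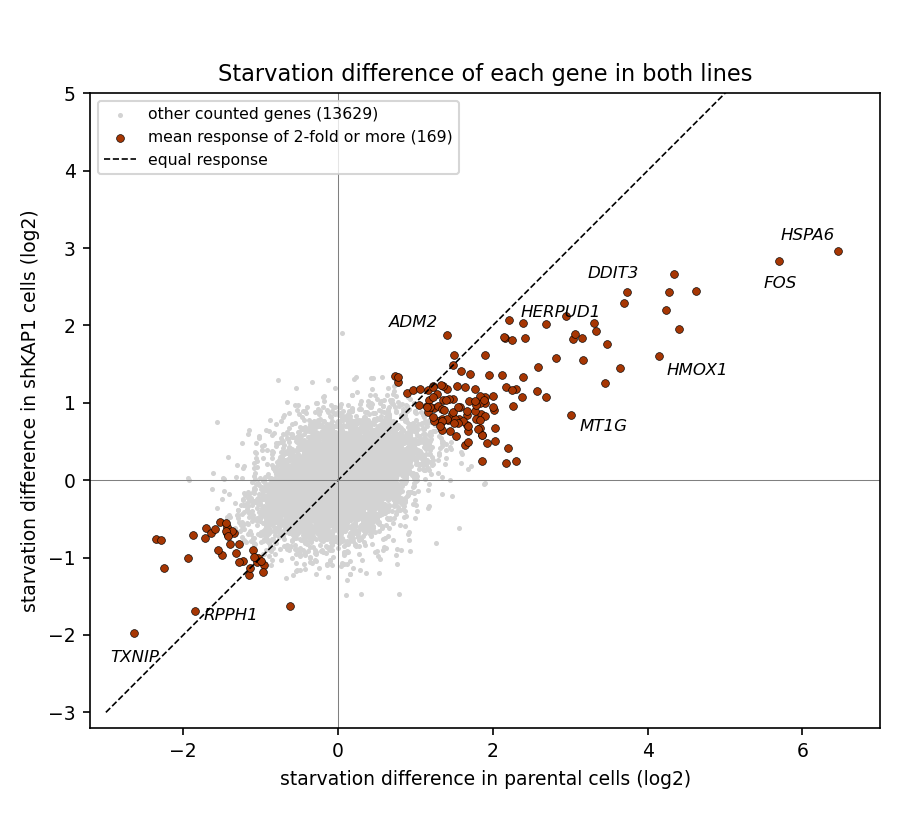
Log2 starvation difference in knockdown cells (vertical axis) against that in parental cells (horizontal axis), 1 point per gene, with the 169 responding genes marked and the diagonal of equal responses drawn. Of the marked genes, 154 had the smaller response in knockdown cells.

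The knockdown difference with glucose asks what loss of KAP1 changes in fed cells. Fed knockdown cells carried more transcript for SCG5, ABCA1, ALOX5AP and several cytokine genes, and less for CCL2 and CALB2. SCG5, a secretory granule chaperone gene, was 12.5-fold higher (3.65, interval 3.33 to 3.97), and the cholesterol exporter gene ABCA1 was 10.0-fold higher (3.32, interval 3.08 to 3.56). ALOX5AP, needed for leukotriene synthesis, was 7.82-fold higher, the interleukin gene IL6 4.71-fold (interval 1.98 to 2.49) and the glycerolipid synthesis gene GPAM 4.56-fold. CCL2 was 11.7-fold lower (-3.55, interval -3.82 to -3.27), the calcium-binding protein gene CALB2 7.72-fold (a second probe gave only -0.21), the phosphodiesterase gene PDE1C 5.17-fold, SEMA3A, an axon guidance gene, 4.55-fold and the laminin gene LAMA5 3.98-fold lower.

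Inflammatory, stress and HIF target lists had positive medians in fed knockdown cells. Of 26 inflammatory genes, 11 were at least 1.5-fold higher and 3 lower, with a median of 0.32 (percentile 100), IL1A 4.47-fold higher and IL1B 2.81-fold higher. Integrated stress response targets had a median of 0.29 (percentile 100), 12 of 33 at least 1.5-fold higher and 0 lower, with DDIT3 at 1.60 and TRIB3 at 1.07. Endoplasmic reticulum genes had a median of 0.35 (percentile 100), with HERPUD1 at 1.39 and DNAJB9 at 1.21. HIF targets had a median of 0.44 (percentile 100), 6 of 19 at least 1.5-fold higher and 1 lower, with LOX 4.24-fold, ANGPTL4 2.79-fold and the angiogenic growth factor gene VEGFA 2.19-fold higher. NRF2 targets had a median of 0.21 (percentile 99.6), with HMOX1 at 1.60 and FTH1 at 0.93, and mesenchymal genes 0.13 (percentile 97.2), with TGFBI at 1.30, THBS1 at 1.09 and SNAI2 at 1.0. DNA replication genes had a median of -0.18 (percentile 0.07), with 26 of 41 below 0, 15 above and 2 at least 1.5-fold lower, E2F1 at -0.68, ORC1 at -0.64 and MCM3 at -0.56. Respiratory chain genes had a median of -0.06 (percentile 2.0, but 6.05 with the mean of all probes). The medians were 0.10 for immediate early genes (percentile 94.2), with EGR1 at 1.21 and FOS at 1.14, and 0.01 for heat shock genes (percentile 56.7), with HSPA6 at 1.92. Glycolysis (0.05, percentile 79.5), aminoacyl-tRNA synthetases (0.09, percentile 91.1), the TXNIP family (0.16, percentile 80.7), mitosis (-0.01, percentile 43.2), p53 pathway (0.09, percentile 85.8), interferon (-0.06, percentile 25.7) and autophagy genes (0.09, percentile 94.7) lay inside the central range of random lists. So did cholesterol (-0.03, percentile 32.6), fatty acid synthesis (-0.06, percentile 22.8), pentose phosphate (0.03, percentile 62.8) and hexosamine genes (0.01, percentile 57.2, negative with median scaling). In all, 158 genes were at least 2-fold higher and 160 at least 2-fold lower, 318 together, of which 93 and 83 were detected on both arrays. Without background correction 69 passed, and at 1.5-fold the counts were 783 and 799.

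The knockdown difference between the starved cultures used the other pair of arrays. ALOX5AP (3.21, interval 3.03 to 3.38) and ABCA1 (3.16, interval 2.95 to 3.38) led the genes detected on both of these arrays, 9.22-fold and 8.97-fold above starved parental cells, followed by LOX at 4.29-fold and GPAM at 4.08-fold. CALB2 was 7.13-fold (a second probe gave only -0.42), PDE1C 5.95-fold, CCL2 5.21-fold, the endothelial proteoglycan gene ESM1 4.98-fold and the cyclin gene CCND2 3.77-fold lower. HIF targets had a median of 0.76 (percentile 100), with 13 of 19 at least 1.5-fold higher and 1 lower, NDRG1 3.10-fold and the carbonic anhydrase gene CA12 2.67-fold higher. Glycolysis genes were higher, with a median of 0.22 (percentile 100), 21 of 23 above 0, PFKFB4 at 1.24, SLC2A3 at 0.87 and ENO2 at 0.74, and so was the TXNIP family (0.73, percentile 100), with TXNIP at 0.77. Both lists were lower after starvation in parental cells, with medians of -0.17 and -0.89, against 0.01 and -0.14 in knockdown cells. The parental starvation values and those given here share the array of starved parental cells. Immediate early genes had a median of -0.18 (percentile 0), with 25 of 33 below 0, 9 at least 1.5-fold lower and 0 higher, FOS at -1.72, the RNA-destabilizing protein gene ZFP36 at -1.32 and FOSB at -1.30. Heat shock genes had a median of -0.26 (percentile 0), with 17 of 21 below 0, HSPA1A at -1.65 and HSPA6 at -1.59. Among inflammatory genes (median 0.10, percentile 93.1), IL6 was at 1.55, CSF2 at 1.40 and CSF3 at 1.24. Mesenchymal genes had a median of -0.03 (percentile 26.6), with TGFBI at 1.59 and the protease gene MMP3 at -1.13.

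Stress lists that were higher in fed knockdown cells were nearer to 0 when both lines were starved. The integrated stress response median was 0.01 (percentile 49.8, turning to -0.08 with median scaling), with GDF15 at 0.71 and TRIB3 at 0.64, and the endoplasmic reticulum median was 0.25 (percentile 100), with WFS1 at 0.74. NRF2 targets had a median of -0.02 (percentile 34.3), with HMOX1 at -0.94. Aminoacyl-tRNA synthetases (0.15, percentile 99.7) and autophagy genes (0.13, percentile 99.6) lay above random lists, with the lysosomal enzyme gene HEXA at 0.83 and GABARAPL1 at 0.87. DNA replication (-0.10, percentile 0.95, or 3.1 with the mean of all probes), mitosis (-0.13, percentile 0.19) and p53 pathway genes (-0.15, percentile 1.64, or 14.7 with the mean of all probes) lay lower than random lists, with CENPF at -0.53, GADD45B at -0.67 and the cell cycle inhibitor gene CDKN1A at -0.63. Cholesterol (0.08, percentile 87.8), hexosamine (0.07, percentile 83.9), pentose phosphate (0.10, percentile 85.2), respiratory chain (-0.03, percentile 11) and interferon genes (0.05, percentile 75.2) lay inside the central range, and fatty acid synthesis genes lay at percentile 46.3; of these, all but the respiratory chain median changed sign with median scaling. In all, 95 genes were at least 2-fold higher and 130 at least 2-fold lower, 225 together, of which 46 and 79 were detected on both arrays. With median scaling the split was 89 and 180, without background correction 63 passed, and at 1.5-fold the counts were 604 and 611.

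**Figure D3:**
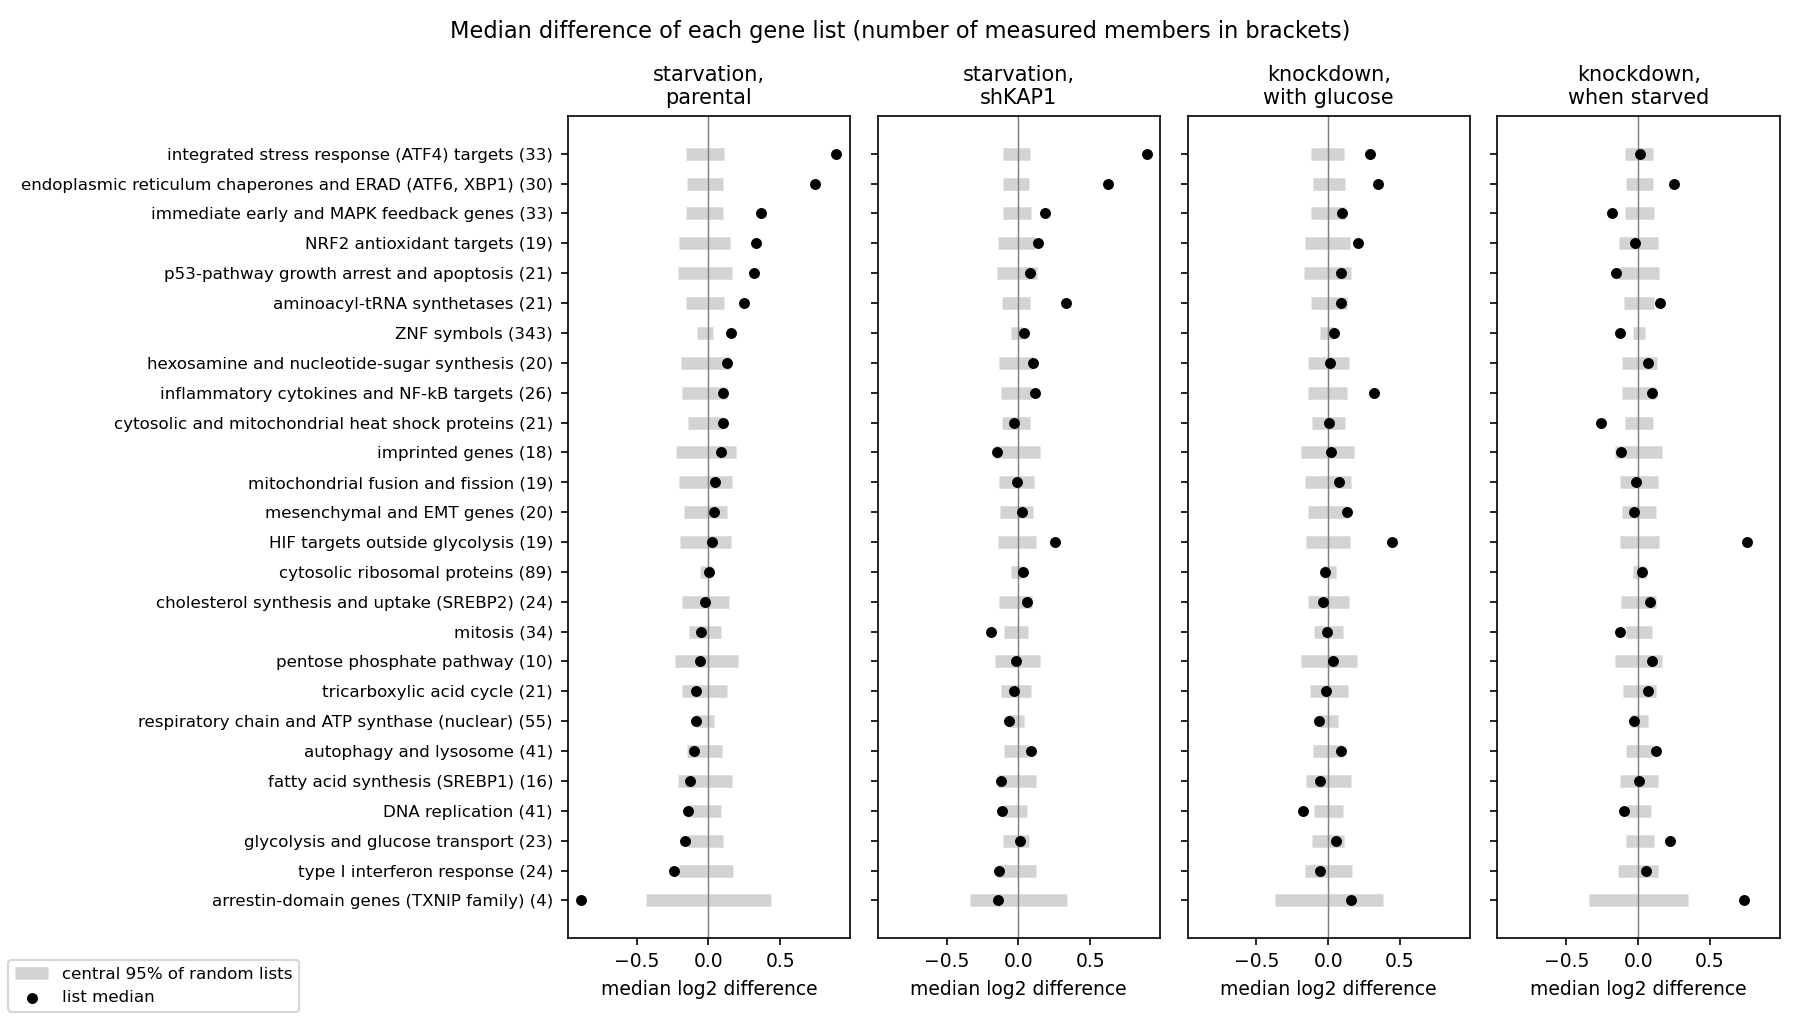
Median log2 difference (horizontal axis) of the gene lists named on the vertical axis, other-cell markers left out, in 1 panel per comparison, with points for the list median and grey bars for the central 95% of random lists matched on expression. Integrated stress response targets lie at 0.89 and 0.90 for starvation in the 2 lines, and HIF targets at 0.44 and 0.76 for the knockdown; respiratory chain genes lie at -0.09 for starvation of parental cells, which turns to 0.04 with median scaling.

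The 2 knockdown differences share no array, and 40 genes were at least 2-fold higher in both, where independent lists would share 1.09. Another 50 were at least 2-fold lower in both, where 1.51 would be shared, and 3 (FOS, HSPA6 and MT1P3) were higher with glucose and lower when starved, with r of 0.391 across genes. The knockdown effect averaged over both conditions was tested with limma, where the residual is the disagreement between conditions. After adjustment over 13798 genes, limma called 30 genes, 16 higher and 14 lower, two-sided, and 1814 lay at an unadjusted p under 0.05. With an intensity trend and a robust prior limma called 703 genes. TRIM28 fell by 3.27 ± 0.14 (SE, adjusted p 0.0164 by limma). ABCA1 rose by 3.24 ± 0.14 and ALOX5AP by 3.09 ± 0.15, and CALB2 fell by 2.89 ± 0.14, each with an adjusted p of 0.0164 in limma, the CALB2 value resting on 1 of its 2 probes. GPAM rose by 2.11, LOX by 2.09, the sphingolipid synthesis gene SPTLC3 by 1.69 and the chromatin reader gene SP140 by 1.71. C3, the central complement gene, rose by 1.95 but was undetected in parental cells, which bounds it at 2.72-fold or more with glucose and 2.52-fold or more without. PDE1C fell by 2.47, CCND2 fell by 1.92 and LAMA5 fell by 1.84. SEMA3A also fell, and was undetected in starved knockdown cells, where it was at least 4.16-fold lower. TFF2, CADM1, a cell adhesion gene, and SPNS2, a sphingosine phosphate transporter gene, fell below detection in the knockdown line, with bounds of at least 3.96-fold, 3.61-fold and 3.81-fold lower with glucose. Each of the called genes named here had the same direction in both conditions, 2 of 2 pairs of arrays, which the fit selects for, since its residual is the disagreement between conditions. In simulated data with no difference between conditions the same fit called 22.4% of planted log2 knockdown effects of 1 and 94.0% of those of 2. The simulated noise followed the prior of the fit and did not depend on intensity, so these rates may not hold for the real arrays.

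Adjusted over the list alone, 12 HIF targets passed limma as higher in the knockdown average and 1 (KDM4B) as lower, against 1 (LOX) over all genes. By the same count, 7 inflammatory genes, IL6 and IL1A among them, passed as higher and 3 (CCL2, NFKB1 and IL11) as lower. Of the mesenchymal genes, TGFBI, SNAI2 and MMP14 passed as higher and CDH11, S100A4 and ZEB1 as lower. KDM4B, NFKB1, IL11, MMP14 and ZEB1 are named after their values were seen. The integrated stress response targets TRIB3, VLDLR, STC2 and GDF15 passed as higher adjusted over the list alone, and so did SLC2A3, ARRDC4 and ABCC3 in their lists. GPAM was the single fatty acid synthesis gene called over all genes.

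Genes of mitochondrial shape and of the KAP1 pathway itself were read in all 4 arrays. The mitofusin gene MFN2 had log2 levels of 8.95 and 8.84 in fed and starved parental cells and 8.42 and 8.79 in knockdown cells. Its knockdown difference with glucose was -0.53 (interval -0.75 to -0.30), and its starvation difference was 0.36 in knockdown cells (interval 0.13 to 0.60). MFN1 was at 6.61, 6.93, 6.78 and 6.39 in the same order, with a knockdown difference of -0.54 after starvation (interval -0.88 to -0.20). OPA1, of inner membrane fusion, was at -0.43 in that comparison (interval -0.61 to -0.25), and the fission gene DNM1L lay between 9.62 and 9.90 on all arrays. The 19 fusion and fission genes had medians of 0.04, -0.01, 0.08 and -0.02 for starvation in parental cells, starvation in knockdown cells, knockdown with glucose and knockdown when starved, at percentiles 77.6, 53.4, 84.0 and 35.7; the second turned positive with median scaling. In the same order, tricarboxylic acid cycle genes lay at percentiles 22.6, 42.6, 38 and 84.8, with 0 genes at 1.5-fold, OGDH lying at -0.51 in starved parental cells, and their medians other than the third changed sign with median scaling.

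Zinc finger proteins with a KRAB domain bind KAP1, and 343 genes with a ZNF symbol were measured, a list not limited to those with that domain. Their median was 0.16 for starvation in parental cells (percentile 100), with 71 at least 1.5-fold higher and 13 lower. It was 0.04 for starvation in knockdown cells (percentile 99.1, or 97.2 with the mean of all probes), with 29 and 13. For the knockdown it was 0.04 with glucose (percentile 97.7, or 95.3 without background correction), with 32 higher and 26 lower, and -0.13 when starved (percentile 0), with 11 higher and 31 lower. The opposite signs of the first and the last value share 1 array, that of starved parental cells. ZNF165 was 5.31-fold higher after starvation in parental and 3.58-fold higher in knockdown cells, and passed limma adjusted over the list alone. ZNF84 was at -1.17 in fed knockdown cells, and ZNF583 was 3.03-fold lower in starved knockdown cells. The 18 imprinted genes, some of which KAP1 is reported to silence, had medians of 0.08, -0.15, 0.02 and -0.12 in the order used for fusion genes, at percentiles 84.4, 4.14, 62.7 and 6.94, with SNURF at -0.85 in starved knockdown cells.

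Control lists were read the same way in that order. The 89 ribosomal protein symbols, 11 of which end in a pseudogene number, had medians of 0.00, 0.03, -0.02 and 0.03, at percentiles 83.1, 98.8, 12.5 and 85.2. With median scaling the second was at percentile 89.7 and the last 2 medians changed sign. Markers of other cell types were few. The 9 measured luminal markers lay at percentiles 83.8, 50.5, 88.7 and 24.6, with XBP1 at 1.32 in starved parental cells and KRT19 at -0.87 in starved knockdown cells. The 11 leukocyte markers lay at percentiles 90.4, 92.6, 29.4 and 94.1, with LCP1 at 1.07 in starved parental cells and CSF1R, undetected in parental cells, at least 1.65-fold higher in fed knockdown cells. The 3 kidney and neuronal markers lay at percentiles 6.70, 87.3, 55.3 and 95. Adjusted over the list alone, limma called XBP1 as higher for starvation and CSF1R as higher for the knockdown. Over 29 lists and 4 comparisons, 45 of 116 medians lay outside the central 95% of random lists. The comparisons share arrays, and random lists of unrelated genes cover neither co-regulation of members nor array error. All percentiles given here therefore only describe these arrays.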

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

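The tests of explanations in this part were all chosen after the result was seen; the search for genes whose starvation difference has opposite signs in the lines, at 1.5-fold or more in both, was set before the data were examined. That search found 40 genes, of which 3 are named under the naming rule. The ribosomal pseudogene RPL31P49 was at 0.79 in parental and -1.47 in knockdown cells, a difference of -2.26, but its parental bead interval, -0.76 to 2.34, holds 0. PAFAH1B2, a platelet-activating factor hydrolase gene, was at -0.64 in parental and 0.87 in knockdown cells, a difference of 1.51 (bead interval 0.87 to 2.15). ZNF714 had a computed difference of -1.84, but it was undetected in fed parental and starved knockdown cells, so starvation is bounded at no less than 1.11-fold higher in parental and 1.58-fold lower in knockdown cells, and the parental bound is under 1.5-fold. None of these 3 differences was tested, since each group has 1 array, and no explanation was weighed for them.

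Of 169 responding genes, 154 (91.1%) responded less to starvation in the knockdown line. With both differences at equal SD over all genes the share was 63.6% (95% bootstrap interval 56.2% to 71.0%), and at equal median absolute deviation it was 64.6%. Equal spreads would also remove a true response that is weaker by the same factor in all genes. A wider spread of all differences between the parental arrays therefore cannot be told apart from a biological difference with 1 array per group. The interval resamples genes and does not cover array error. With the spreads left as they were, the share stayed between 90.5% and 96.6% over 5 settings, which argues against quantile scaling or background correction as the whole cause. Only median scaling replaced the quantile step. The value table gave nearly the 2-fold counts of quantile normalization without background correction, 163 and 163 probes for starvation in parental cells, so it adds little to that setting. The settings also include a gene filter, and none was meant to equalize the spreads, so other effects of normalization stay open. Unstarved RNA mixed into the starved knockdown sample would, as the only cause, shrink all linear responses alike. The ratio of responses was higher by 0.242 in 25 stress-response and chaperone genes than in 13 immediate early and heat shock genes. Its 95% bootstrap interval was 0.0833 to 0.442. This argues against mixing alone, but the groups were chosen after the result was seen and the interval does not cover array error. Mixing beside a true difference between the groups stays open. Split into parts, the difference of responses between the lines lay mostly with glucose for the 25 stress-response and chaperone genes (glucose part minus starved part 0.61, interval 0.46 to 1.16). For the 13 immediate early and heat shock genes the same value was -0.68 (interval -1.20 to 0.0046), with median knockdown differences of 0.15 with glucose and -0.82 when starved. Both parts only divide the observed difference, the first resting on the fed pair of arrays and the second on the starved pair. A higher level with glucose cannot be told apart from an error of a fed array, nor a lower level when starved from an error of a starved array. A weaker or shorter starvation of the knockdown culture stays open, because the TXNIP response was also smaller, by 0.67 (bead interval 0.38 to 0.95), and an effect of KAP1 on TXNIP would look the same, as would an effect of the hairpin vector, for which there are 0 control arrays. List medians went both ways. In knockdown against parental cells they were 0.90 against 0.89 for integrated stress response targets and 0.33 against 0.25 for aminoacyl-tRNA synthetases. The means of these lists were 0.91 against 1.24 and 0.30 against 0.21. Of the 25 stress-response and chaperone genes, 23 had the smaller response in knockdown cells, so the near-equal stress response medians do not show an equal response. Medians were smaller in knockdown cells for endoplasmic reticulum genes (0.63 against 0.74) and immediate early genes (0.19 against 0.36).

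Genes with a ZNF symbol were higher on the array of starved parental cells than on those of fed parental and starved knockdown cells. The normalization as the whole cause is argued against by the list median, at 0.09 to 0.30 over 4 settings and at percentile 100 in each. Dim probes near background are argued against by the 261 members detected on all 4 arrays, whose median was 0.16 (percentile 100). A property of that 1 array cannot be told apart from a starvation effect, because the knockdown line gave a median of only 0.036 (percentile 99.1) and no second array of starved parental cells exists. A weaker response of ZNF genes to starvation without KAP1 may also explain the pattern and stays untested.

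HIF targets outside glycolysis were higher in knockdown cells both with and without glucose. The normalization as the whole cause is argued against by the list medians, at 0.35 to 0.70 over 4 settings and both comparisons, each at percentile 100. Oxygen shortage in the knockdown cultures cannot be told apart, because the glycolysis genes, which it would also raise, had a median of 0.051 with glucose (percentile 79.5) over members that went both ways, but 0.22 when starved (percentile 100), with 21 of 23 above 0. The value when starved rests on the array of starved parental cells, where glycolysis genes were also lower than with glucose (median -0.17). A higher level of EPAS1, which encodes HIF-2 alpha and was looked up after its values were seen, may contribute, since its average knockdown difference was 1.60 (1.67 with glucose and 1.53 without). Clonal drift of the knockdown line and effects of the vector stay open and untested, with 0 nontargeting arrays.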

How the results depend on the processing

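The alternatives were set before the data were examined, except eBayes with a trend alone and the response size in genes detected on every array, which were chosen after seeing the data. Counts are given in the order starvation in parental cells (436), starvation in knockdown cells (168), knockdown with glucose (318), knockdown when starved (225) and difference of responses (397). Without background correction they were 134, 40, 69, 63 and 35; with an offset of 50, 222, 67, 129, 92 and 73; and in the authors' value table over all probes, 163, 52, 85, 75 and 45. Each of these pulls differences of dim probes toward 0 by construction. At 1.5-fold they were 2053, 1109, 1582, 1215 and 1929, and at 3-fold 100, 31, 64, 40 and 50. Only genes detected on every array gave 86, 172, 117 and 119 for all but the first, and 299 for the first. These counts fell by a larger share than the genes did, from 13798 to 11532. Many of the 2-fold differences thus lay in genes undetected on at least 1 array.

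The limma count for starvation went from 0 to 1241 without background correction, 584 with an offset of 50, 2309 in the value table, 245 in genes detected on every array, 981 with a trend and robust prior and 1054 with a trend alone. The limma count for the knockdown went from 30 to 829, 396, 1571, 122, 703 and 713 in the same order, 46 with the mean of all probes of a gene, 56 at an adjusted p under 0.1, and 18 with a minimum fold of 1.2, the last 2 by construction. The cause of the other changes was not tested. All 30 genes were among the calls without background correction, with the offset of 50 and with either trend fit, and 29 with median scaling. Among genes detected on every array 17 were called again, which are all of the 30 so detected. The others were undetected on at least 1 array and could not enter that count.

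The TRIM28 difference with glucose went from -3.30 to -2.45 without background correction and -2.94 with an offset of 50, and when starved from -3.24 to -2.36 and -2.86, staying negative. Shared starvation genes (77) were 37 without background correction and 48 in the value table. Shared knockdown genes (90) were 40, 52 with an offset of 50 and 47 in the value table. The share of genes with a smaller response in knockdown cells (91.1%) was 95.8% without background correction and 96.6% in the value table; the cause was not tested.

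Median scaling in place of quantile moved the median of all genes from -0.03 to 0.12 on the log2 scale for starvation in parental cells. It reversed the respiratory chain median there, from -0.09 to 0.040, although its percentile was 2.35, so relative to other genes the list stayed low. Counts under median scaling were 508, 180, 294, 269 and 417. The main splits of 273 and 163, 111 and 57, 95 and 130 and 181 and 216 became 396 and 112, 137 and 43, 89 and 180 and 140 and 277, leaving out the knockdown with glucose. Dropping the detection filter gave 438, 169, 322, 225 and 535 genes, and the mean of all probes 407, 166, 302, 211 and 373. Of 1758 further values of named genes, 1478 moved within their spread, 280 moved beyond it and 0 of those at 2-fold or more reversed; of 464 list medians, 400, 63 and 1, where a change of sign counts as reversed only if the median first lay outside the central range of random lists. Other medians near 0 also changed sign. Lists that left the random range under an alternative included, with no background correction, hexosamine genes for starvation in parental cells (percentile 97.7) and interferon genes in knockdown cells (0.4), and, with the mean of all probes, immediate early genes for the knockdown with glucose (98.7).

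The value table shares no probe identifiers with the main table, so TRIM28, named genes and lists were not run with it. No paired analysis was possible because each group has 1 array and no replicate numbers pair samples, beyond the terms for line and starvation that the limma fit already holds, and for that reason leaving out an array was not possible either. Signal over background limits the dim genes: 13798 genes were detected on at least 1 array and 11532 on all 4.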

Other observations

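The gene families in this part were chosen after their values were seen. Metallothioneins are proteins that bind zinc and copper. Of the 7 family symbols measured, MT1IP and MT1P3 are pseudogenes, and they gave the largest differences after starvation of parental cells, 3.64 and 4.40. The 7 had a median log2 difference of 3.02 in that comparison (percentile 100 of 2000 random lists), all 7 at least 2-fold higher, from 1.15 to 4.40. In knockdown cells their starvation median was 1.07, with 4 at least 2-fold higher. The knockdown median was 0.95 with glucose and -0.65 when starved (percentile 0). No median changed sign with median scaling, an offset of 50 or no background correction. Members are close in sequence, so they are not independent readings.

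The 33 histone genes had a median of -0.56 in fed knockdown cells against parental cells, with 28 below 0 and 5 above, 14 at least 1.5-fold lower and 1 higher; being chosen for its values, the family has no independent test. When both lines were starved the median was -0.31, with 26 below 0 and 7 above, 11 at least 1.5-fold lower and 1 higher. The first median was -0.28 without background correction, -0.54 with median scaling and -0.39 with an offset of 50, and the second -0.16, -0.41 and -0.23. The linker histone gene H1-2 was at -1.63 and -1.24, H2AC6 at -1.65 and -0.93, and H2AC18 at -1.43 and -1.20. Starvation gave histone medians of -0.10 in parental cells (percentile 15.8, turning to 0.01 with median scaling) and 0.08 in knockdown cells (percentile 89.9). Most histone transcripts carry no poly(A) tail, and their paralogs are close, so these values are uncertain. The 37 proteasome genes served as a comparison, with 0 at 2-fold in any of the 4 differences.

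Where other probes of a gene at 2-fold or more were detected, most had the sign of the probe used: 117 of 122 other probes for starvation in parental cells, 32 of 36 in knockdown cells, 65 of 72 for the knockdown with glucose and 45 of 47 when starved. Fewer reached 1.5-fold the same way, 87, 28, 50 and 34 in that order, and 2, 0, 1 and 0 were at 1.5-fold the other way.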
